A study of Mus musculus with 24 samples.

How the data were processed

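RNA was sequenced from 24 mouse cerebral cortices, 6 in each of 4 groups of males: wild type (WT) or Mecp2 null (KO in the group names), each given recombinant human nerve growth factor (rhNGF) or phosphate-buffered saline (vehicle) through the nose from postnatal day 30 to postnatal day 60, the day of dissection. Per the labels' protocols, total RNA with an integrity number above 7 was used, and stranded polyA libraries were made from 1000 ng. The submitters' processing notes name fastp, STAR, RSEM, DESeq2 and the genome build GRCm38 without versions, roles or order, and the aligner's settings, the annotation and the strand setting of the counting are not given in the sources used here.

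The deposited table, although named as raw counts, holds TPM, a unit normalized to transcript length and library total: each library sums to 1000000 within 2 units, the values have 2 decimals, and 99.0 to 99.3% of the values above 0 in a library are not whole. TPM keep no sequencing depth, so the depth of the libraries is unknown, no interval from counting error can be given, and a fold change of a low gene is less certain than its TPM shows. The table lists 55487 gene identifiers, of which 55227 matched GENCODE mouse release M21 on GRCm38, which gave the symbols, types, coordinates, spans, transcript lengths and GC content. All 24 columns matched a sample label. No pair of libraries held identical values. The Pearson correlation of log2 values over genes between libraries was 0.938 to 0.985 within groups and 0.918 to 0.984 between groups. The labels do not say outright that each library is a separate animal, and p-values measure the spread between these libraries.

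Before the data were examined, the groups, the comparisons, 40 gene lists, the rule for named genes and some of the alternatives (listed below) were fixed, with a test for counts. Because the unit is TPM, limma 3.58.1 in R 4.3.3 was used in its place. TPM were divided by trimmed-mean (TMM) factors between libraries (own code without weights, 30% of the log ratios and 5% of the log means trimmed at each end), genes with at least 0.5 TPM in at least 6 libraries were kept (16904 genes, 14303 of them protein coding), and log2(scaled TPM + 1) was fitted with 1 mean per group over all 24 libraries and no covariate, with a trended and robust moderated variance. Fold changes are on this log2(TPM + 1) scale, which understates the changes of low genes, while TPM are printed as deposited, so a ratio of printed TPM can differ from the fold change. P-values were adjusted by Benjamini-Hochberg over the genes of a comparison at a threshold of 0.05. The 5 comparisons were null against WT under vehicle, null against WT under rhNGF, rhNGF against vehicle in null and in WT cortex, and the interaction. Errors of log2 fold changes are limma standard errors, and errors of TPM are SDs over 6 libraries.

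Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 40 lists of a comparison, beside camera with an estimated correlation and limma's fry. Genes were named by this rule: Mecp2, Ngf, Ntrk1, Ngfr, Bdnf, Sgk1, Fkbp5, Crh and Irak1 always. Per comparison the 8 called genes with the largest rise and the 8 with the largest fall were added, among genes with a symbol that is not a predicted or clone name and at least 1 TPM in a group compared (5 in each direction for the interaction). Where none was called, the 5 genes with the smallest p were added, stated as not passing. The 3 members with the smallest p of each list called by camera and up to 3 called members of other lists completed the rule, with 1 gene that it selects left out of the text. Values of single libraries were compared by exact permutation tests, two-sided, with 21 tests in one family.

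Title numbers run from 1 to 24 with none shared between groups, so no samples were paired. Libraries within every group separated by title number, the 3 lowest numbers from the 3 highest (below). No label names a batch. After this was seen, every comparison was also computed within the lower-numbered and the higher-numbered libraries and with that division as a term. A score along this division was made from the 12 WT libraries (the mean over both WT groups of lower-numbered minus higher-numbered libraries, gene by gene, onto which each library was projected). Set beforehand as other ways to compute the results were median-of-ratios and upper-quartile factors, no filter, a filter of 1 TPM, a fit of only the 2 groups compared, and leaving out each library. Chosen after seeing the data were pseudocounts of 0.1 and 0.5 TPM, TPM as deposited, the division as a term, each side of it alone, the score as a covariate, 2 residual principal components, sample quality weights (by the gene-by-gene method, and by the default method, which did not converge), removal of a smooth GC trend from each library, and leaving out the 2 libraries that stood apart. The planned count tests, surrogate variables from counts and voom weights were not run, since TPM are not counts.

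The code was tested on simulated data: in 10 simulations of null against WT under vehicle over 16904 genes with 200 genes changed, 82.2% of changes of 1 and 39.8% of changes of 0.5 on the log2 scale were recovered with independent noise, with 5.8 false calls on average (at most 13), and 81.9% and 42.5% with the real residuals of shuffled libraries, with 7.6 on average (at most 27). False calls under Benjamini-Hochberg depend on the number of genes changed, so these numbers are no estimate for the 32 real calls. For each comparison 100 splits of the libraries were compared, counting the real one. Reads shared between ribosomal protein or mitochondrial genes and their many pseudogene copies were divided by the submitters' quantification, so such genes are less certain.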

Results

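Transcript abundance was measured by polyA RNA sequencing in 24 libraries from the cerebral cortex of male mice at postnatal day 60. Mecp2, an X-linked gene for a protein that binds methylated DNA, was intact in 12 libraries (WT) and inactivated in 12 (null), and 6 libraries of each genotype came from mice given rhNGF, a recombinant form of the neurotrophin nerve growth factor, and 6 from mice given vehicle. The values are in TPM, the length-normalized unit of the deposited table, and the sequencing depth is unknown. Between 13777 and 14940 genes per library had at least 1 TPM. Genes encoded by the mitochondrial genome took 8.42 to 18.6% of a library.

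Libraries differed within groups. The first principal component held 41.1% of the variance, and the residual first component, with 40.7%, placed the 3 lowest title numbers above the 3 highest in 4 of 4 groups. On a score defined from the WT libraries alone, lower-numbered null libraries lay 0.711 above higher-numbered ones (exact permutation p = 0.005 over 400 splits, two-sided), where 1 is the mean difference in WT. Null rhNGF libraries lay 0.522 above null vehicle libraries on this score (exact permutation p = 0.067 over all 924 splits, and 0.01 over the 400 splits that keep the number sets). WT rhNGF and WT vehicle libraries differed by -0.003 (exact permutation p = 0.99). Each comparison below is therefore given also with the number set as a term and within each number set.

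**Figure D1:**
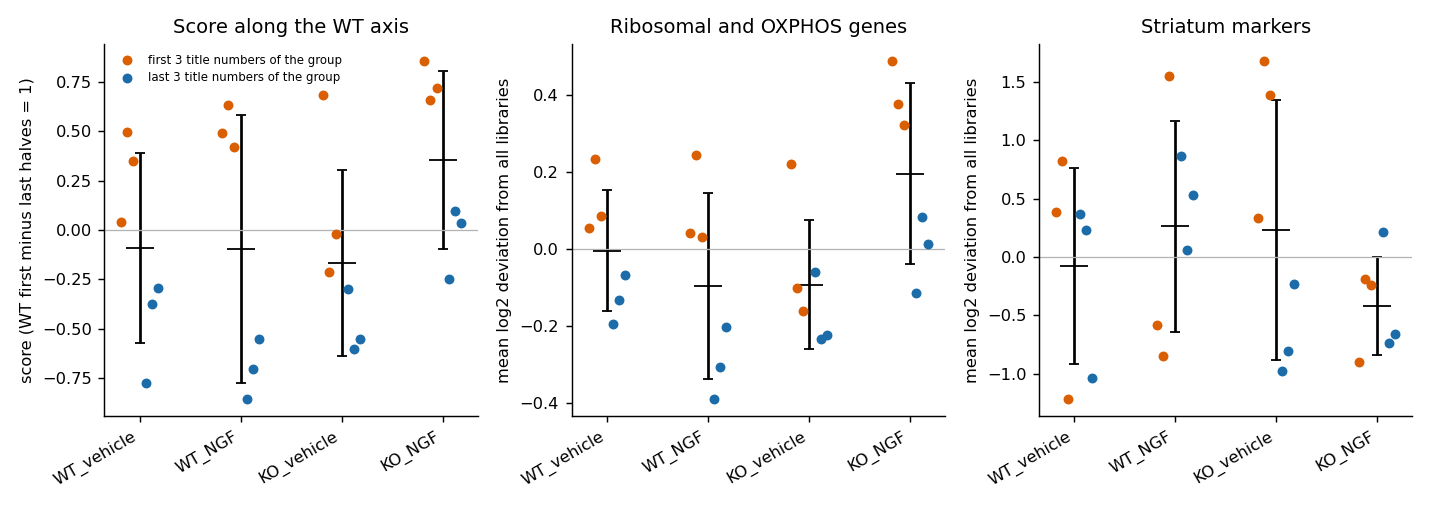
Each point is a library, coloured by whether it has 1 of the 3 lowest or 1 of the 3 highest title numbers of its group, with the mean and SD of each group in black (n = 6). Left, the score along the WT division; middle and right, mean log2 deviations of ribosomal and oxidative phosphorylation (OXPHOS) genes and of striatum markers, which differ by up to 2.66 log2 units within a group.

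Mecp2 itself (chromosome X, 74026592 to 74135363, GRCm38) followed the labels in every library. It was at 24.01 ± 4.67 TPM (SD, n = 6) in WT vehicle and 24.6 ± 5.63 TPM in WT rhNGF cortex, against 2.08 ± 0.365 TPM in null vehicle and 2.24 ± 0.289 TPM in null rhNGF cortex. The log2 difference was -3.05 ± 0.12 under vehicle (limma adjusted p = 6.4e-14) and -2.90 ± 0.12 under rhNGF (adjusted p = 2.0e-13), lower in 6 of 6 null libraries each time.

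The comparison of null with WT cortex under vehicle asks what loss of Mecp2 changes. Of 16904 genes tested, 12 were higher and 20 lower in null cortex by limma (1109 at an unadjusted p under 0.05). Irak1, a kinase of interleukin-1 receptor signalling and the neighbour of Mecp2 (chromosome X, 74013914 to 74023918), rose 1.88-fold on the scaled log2 scale, from 28.9 ± 3.001 to 57.3 ± 5.62 TPM as deposited (log2 change 0.91 ± 0.07, adjusted p = 2.3e-08). Fkbp5, a co-chaperone of steroid receptors that glucocorticoids induce (chromosome 17, 28399094 to 28517527), rose from 14.1 ± 1.71 to 22.5 ± 3.31 TPM (0.59 ± 0.11, adjusted p = 0.019). Tnnc1, a troponin (chromosome 14, 31208312 to 31211729), fell from 28.7 ± 7.38 to 8.37 ± 2.02 TPM (-1.71 ± 0.24, adjusted p = 0.0018), Fgf11, an intracellular fibroblast growth factor homolog (chromosome 11, 69796068 to 69801857), from 10.8 ± 1.44 to 5.13 ± 1.19 TPM (-1.002 ± 0.13, adjusted p = 0.00058), and Cacna1g, the T-type calcium channel subunit Cav3.1 (chromosome 11, 94408391 to 94474198), from 43.6 ± 6.06 to 26.4 ± 2.23 TPM (-0.74 ± 0.11, adjusted p = 0.0031).

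The other largest rises were in Neat1, a nuclear long noncoding RNA (log2 change 0.83), the chloride channel gene Clcnka (0.74), the adhesion gene Sdk1 (0.71), the BMP-binding protein gene Bmper (0.66), Smoc2 (0.65) and the diacylglycerol kinase gene Dgkg (0.64). The other largest falls were in Adamts13 (-1.005), the neuropeptide genes Tac2 (-1.004) and Grp (-1.001), Plb1 (-0.87) and AW551984 (-0.85). Adjusted p of these genes lay between 0.016 and 0.049, and each of them was shifted in its direction in 6 of 6 null libraries against the WT mean. AW551984 in WT vehicle cortex ranged widely, and its highest library, WT vehicle 2, was at 3.47 TPM. With the number set as a term, 157 genes were called. Within the lower-numbered libraries 2 genes were called (Mecp2 and Hkdc1), and within the higher-numbered ones 7, among them Mecp2, Irak1, Fgf11, Tnnc1 and Neat1; such genes outside the naming rule are given because the counts are small. Without 1 library the count was between 15 and 32, with the lowest counts without WT vehicle 1 (15 genes), WT vehicle 5 (16), null vehicle 12 (18), WT vehicle 2 (19), WT vehicle 3 (19) and null vehicle 9 (20).

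**Figure D2:**
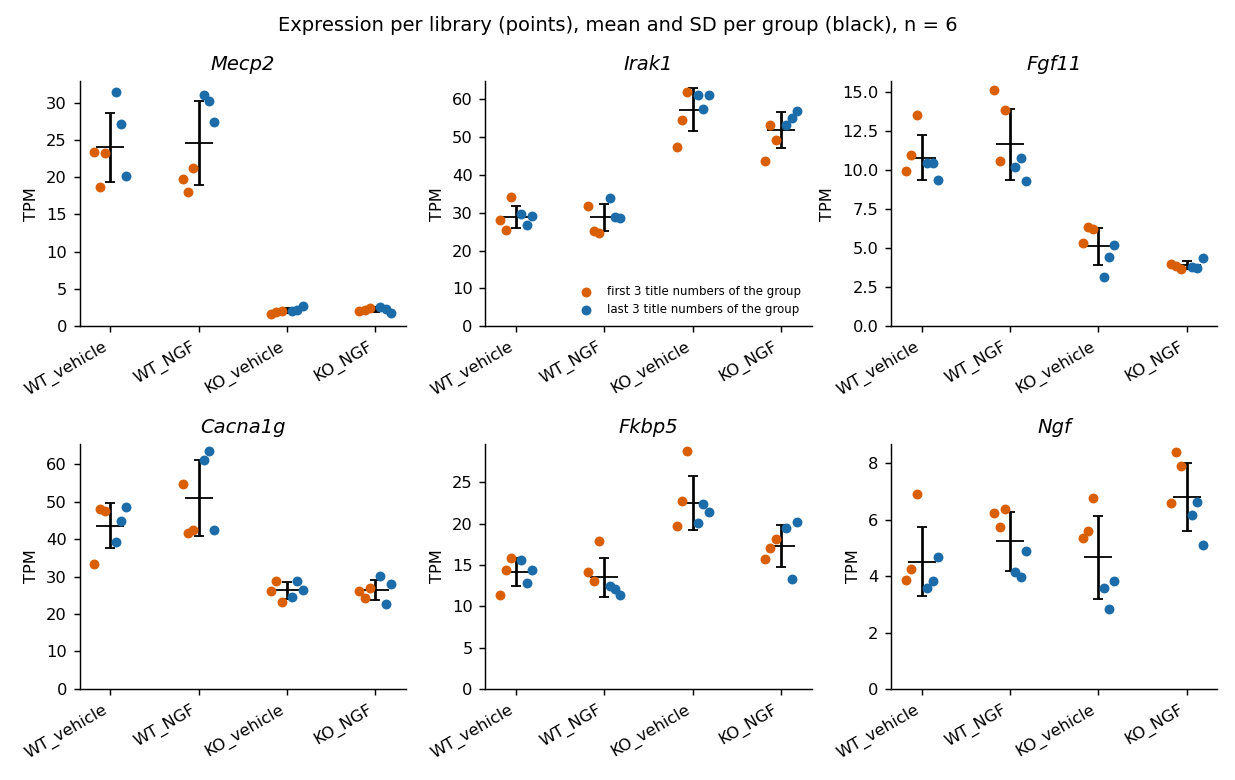
TPM of 6 genes in each library (points, coloured by the lower-numbered or higher-numbered libraries of a group), with the mean and SD of each group in black (n = 6). Mecp2 lies far below the WT libraries in every null library, and Irak1 is 1.88-fold higher in null cortex under vehicle and 1.88-fold under rhNGF.

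Gene lists were described by the median log2 change of their members. By camera with a preset correlation, 8 of 40 lists differed between null and WT vehicle cortex, of which 0 passed with an estimated correlation, and 51 of 100 splits of the same 12 libraries (counting the real one, here and below) called at least as many. Sterol synthesis genes were lower, with 21 of 23 below 0 (median -0.12, camera adjusted p = 0.00012; adjusted p = 0.1 with an estimated correlation, 0.025 by fry). Nsdhl, an X-linked sterol dehydrogenase gene (chromosome X, 72918557 to 72958514), fell by 0.46 on the log2 scale (adjusted p = 0.0092) and was the only called member, also adjusted over the list alone, while Tm7sf2 (-0.40) and Cyp51 (-0.31) did not pass. Under rhNGF the list was not called in null against WT cortex, with 12 of 23 genes above 0 (median 0.03, camera adjusted p = 0.15). Its mean log2 change there was still -0.125, against -0.156 under vehicle. Adjusted over the list alone, 6 members were lower and 0 higher under rhNGF. Oligodendrocyte precursor markers were lower (12 of 14 below 0, median -0.16, camera adjusted p = 0.0018; adjusted p = 0.08 with an estimated correlation, 0.025 by fry). Gpr17 (-0.49), Neu4 (-0.43) and C1ql1 (-0.34) had its smallest p. Of the members, 0 were called over all genes tested and 2 fell when adjusted over the list alone.

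Immediate-early genes, which neuronal activity induces, were lower, with 20 of 25 below 0 (median -0.23, camera adjusted p = 0.00061; adjusted p = 0.79 with an estimated correlation). Egr2 (-1.23), Egr1 (-0.64) and Arc (-1.12) led this list, with 0 calls over all genes tested and 1 adjusted over the list alone. Null vehicle 10 and 11 stood low: Arc was at 59.6 and 42.05 TPM there against 95.3 to 213 TPM in the other 4, and Fos, given because these libraries were seen, at 8.65 and 7.54 against 20.1 to 45.9 TPM. The glucocorticoid response list was higher, with 13 of 18 above 0 (median 0.09, camera adjusted p = 0.017; adjusted p = 0.64 with an estimated correlation). Beside Fkbp5, the lipid droplet gene Plin4 (0.58, adjusted p = 0.057) and Crh, corticotropin-releasing hormone (-0.81, adjusted p = 0.073), had its smallest p. Of the members, 2 rose and 1 fell when adjusted over the list alone. Sgk1, a kinase gene that glucocorticoids induce, was at 51.8 ± 6.85 TPM in WT and 67.3 ± 10.2 TPM in null vehicle cortex (0.32 ± 0.12, adjusted p = 0.44).

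Of the other called lists, medians were -0.09 for complex I (34 of 37 below 0; Ndufa1 -0.21, Ndufa4 -0.15, Ndufa3 -0.23), -0.10 for complexes II to V (36 of 40; Cox7c -0.24, Atp5e -0.64, Cox6c -0.17) and -0.07 for chaperones (15 of 23; Manf -0.28, Sdf2l1 -0.43, Dnajb11 -0.14). Meningeal fibroblast markers, which a dissection of cortex can carry, were higher (16 of 16 above 0, median 0.31, with Fmod 0.77, Ptgds 0.95, Slc22a6 0.48). Camera adjusted p of these 4 lists lay between 9.6e-05 and 0.0095, and between 0.64 and 0.89 with an estimated correlation. None of the named members of these 4 lists passed over all genes tested. Of the 24 named members of the 8 lists, 7 passed with the number set as a term: Nsdhl, Fkbp5, Gpr17 (adjusted p = 0.01), Neu4 (0.036), Plin4 (0.025), Crh (0.02) and Sdf2l1 (0.032). The neurotrophin genes showed no call under vehicle: Ngf -0.02 ± 0.18, Bdnf -0.05 ± 0.26, and the receptor genes Ntrk1 -0.004 ± 0.18 and Ngfr 0.02 ± 0.19, the last pair near or below 1 TPM.

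Genes with a span over 100 kb (2255 genes) had a median log2 change 0.063 above that of the 14623 other genes in null vehicle cortex (camera p = 1.1e-05; p = 0.19 with an estimated correlation). Under rhNGF, null against WT cortex gave -0.21, opposite in sign (camera p = 2.0e-06, and 0.16 with an estimated correlation). The same difference was -0.28 for rhNGF in null cortex (camera p = 1.2e-11, and 0.05 with an estimated correlation). It was 0.006 for rhNGF in WT cortex and -0.29 for the interaction. Among 40 divisions of libraries of the same group, each 3 against 3, the difference ran from -0.34 to 0.17, and 31 were as large in size as 0.063. Means of 3 libraries vary more than the means of 6 in the comparisons, so this spread is wider than the matching one. Beyond -0.28 lay -0.34 in WT rhNGF libraries and -0.324 in null rhNGF libraries. Both are the division of the lower-numbered from the higher-numbered libraries, so they carry the separation by title number described above.

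**Figure D3:**
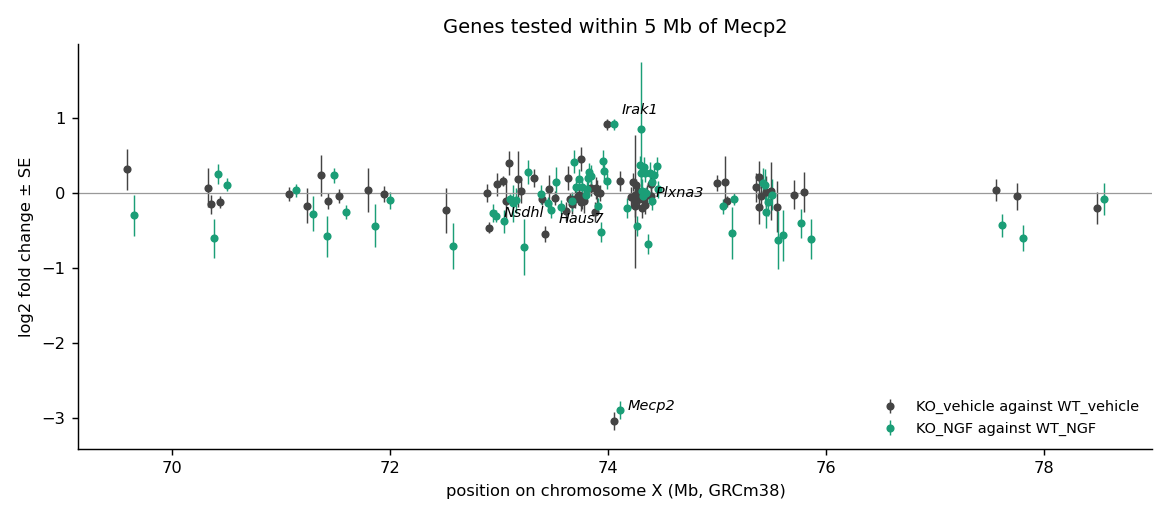
Log2 fold changes with their SE of the genes tested within 5 Mb of Mecp2, at their positions on chromosome X, for null against WT under vehicle (grey) and under rhNGF (green, drawn slightly to the right). Named are the genes called in either comparison: Mecp2, Irak1, Nsdhl, Haus7 and Plxna3.

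The same genotypes compared under rhNGF used other libraries. Here 54 genes were higher and 47 lower in null cortex (4208 at an unadjusted p under 0.05), and 5 of the rises and 6 of the falls were also called under vehicle, against 0.038 and 0.056 for unrelated lists of these sizes. With the number set as a term, 26 of the rises and 34 of the falls were shared, against 9.79 and 13.6. These expected numbers take both lists as independent, although both came from the same fit with a shared variance per gene. Mecp2, lost by design, is counted among the falls. The shared genes were Mecp2, Irak1, Fgf11, Tnnc1, Cacna1g, Clcnka, Sdk1, Bmper, Smoc2, AW551984 and the predicted gene Gm42884. Of the 32 genes called under vehicle, Mecp2 itself among them, 30 kept their sign, and the correlation of their log2 changes across genes was 0.87. Mecp2, at -3.05 under vehicle and -2.90 under rhNGF, weighs on this correlation, which was not computed without Mecp2. Over all genes tested the correlation was -0.002, and genes are not independent replicates. The median size of the changes of the 32 genes was 0.727 under vehicle, where they were selected. Their median change in the same direction under rhNGF was 0.319. Irak1 rose again from 28.8 ± 3.55 to 51.9 ± 4.76 TPM (0.91 ± 0.07, adjusted p = 2.3e-08), Fgf11 fell from 11.6 ± 2.29 to 3.92 ± 0.257 TPM (-1.27 ± 0.13, adjusted p = 8.1e-06), and Cacna1g changed by -0.83 ± 0.11 (adjusted p = 0.00059).

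Other large rises under rhNGF were in Clcnka (1.03), the presynaptic gene Rims3 (0.85), Fam43a (0.83), Sdk1 (0.76), Pdlim1 (0.75), Nell1 (0.74) and Bmper (0.72). Large falls were in the activity-induced transcription factor genes Egr2 (-1.66) and Nr4a3 (-1.03), the radial glia and astrocyte gene Fabp7 (-1.42), Tnnc1 (-1.23), AW551984 (-0.96) and Slc16a14 (-0.90), and adjusted p of these genes lay between 0.00083 and 0.041. Called members of the fixed lists were also Crh (-0.85, a peptide of interneurons), Plxna3 (-0.68), the glucocorticoid-induced Tsc22d3 (0.58), the oligodendrocyte precursor receptor gene Pdgfra (-0.60), Vamp1 (0.54) and the deep-layer neuron factor Tbr1 (0.42), each shifted in its direction in 6 of 6 null libraries. Fkbp5 did not pass here (0.42 ± 0.11, adjusted p = 0.073), nor did Sgk1 (0.35), Ngf (0.40), Bdnf (-0.48), Ntrk1 (-0.45) or Ngfr (-0.33). The term for the number set gave 5015 calls, 2470 higher and 2545 lower, with 5 within the lower-numbered (Mecp2, Irak1, Fgf11, Fgf20 and Gm3219) and 4491 within the higher-numbered libraries (1842 higher and 2649 lower). Without 1 library the count ran from 31 to 789, with 31 without null rhNGF 21, 33 without WT rhNGF 17, 40 without null rhNGF 20, 41 each without WT rhNGF 16 or 18, 51 without null rhNGF 19, 245 without WT rhNGF 13, 450 without WT rhNGF 14 and 789 without null rhNGF 22.

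Camera called 14 lists in this comparison, and 0 passed with an estimated correlation. Higher in null cortex were the cytosolic ribosome (55 of 57 genes above 0, median 0.34, with Rps25 0.34, Rpl34 0.28, Rpl17 0.23), complex I (0.30, with Ndufb4 0.46, Ndufa6 0.29, Ndufa12 0.38), complexes II to V (0.31, with Sdhc 0.41, Uqcrfs1 0.20, Atp5a1 0.33) and the mitochondrial ribosome (0.24, with Mrps17 0.27, Mrpl13 0.23, Mrps27 0.36). So were glycolysis (0.28, with Slc2a1 0.49, Ldhb 0.38, and Slc16a1 at -0.44), the TCA cycle (0.13, with Fh1 0.26, Pcx 0.45, Sdhb 0.40) and antioxidant genes (0.18, with Gsr 0.36, Sod1 0.37, Sod2 0.21). Camera adjusted p of these 7 lists lay between 3.0e-12 and 0.029, and between 0.45 and 0.47 with an estimated correlation. Lower were voltage-gated channels (-0.27, with Cacna1g, Kcnc2 -0.64, and Scn1b at 0.58), glutamatergic synapse genes (-0.24, with Dlg3 -0.33, Grm3 -0.51, Dlgap2 -0.22) and immediate-early genes (-0.32, with Egr2, Nr4a3 and Egr3 at -0.39). Also lower were markers of hippocampus (-0.26, with Trpc6 -0.72, Calb1 -0.63, Man1a -0.59), striatum (-0.67, with Rxrg -1.08, Pde10a -0.99, Isl1 -0.52), choroid plexus (-0.89, with Enpp2 -1.06, Kl -1.42, Aqp1 -1.01) and basal forebrain cholinergic neurons (-0.49, with Slc5a7 -0.54, Ecel1 -0.77, Ntrk1). Isl1 (0.777 TPM in WT and 0.147 TPM in null rhNGF cortex) and Ntrk1 (0.603 and 0.1 TPM) were low. Camera adjusted p of these 7 lists lay between 0.0013 and 0.043, and between 0.45 and 0.66 with an estimated correlation. Members listed here without a call above did not pass over all genes tested, while with the number set as a term 38 of 42 named members passed (not Rxrg, Pde10a, Isl1 and Ntrk1). Adjusted over the list alone, 12 complex I genes passed, all higher, against 0 of complexes II to V, the cytosolic ribosome, the mitochondrial ribosome, antioxidant genes, striatum and basal forebrain cholinergic neurons, and at most 4 in any other of these lists.

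The comparison of rhNGF with vehicle in null cortex asks what the treatment changes without Mecp2. It called 2 genes, both lower: Myh10, a nonmuscle myosin heavy chain (chromosome 11, 68691559 to 68816632), went from 87.7 ± 11.5 to 60.96 ± 7.36 TPM (-0.40 ± 0.06, adjusted p = 0.022), and Plpp6, a phospholipid phosphatase (chromosome 19, 28963953 to 28966811), from 30.5 ± 3.42 to 20.9 ± 3.02 TPM (-0.41 ± 0.07, adjusted p = 0.022), each in 6 of 6 libraries. At an unadjusted p under 0.05 there were 5992 genes, 3217 higher and 2775 lower. With the number set as a term, 3520 genes were higher and 3358 lower. Within the lower-numbered libraries 3548 genes were called, and within the higher-numbered libraries 0. Leaving out null vehicle 7 gave 5723 calls and leaving out null rhNGF 22 gave 4304, while 0 genes were called without any 1 of null vehicle 8, 9 or 12 or null rhNGF 19, 20 or 23, and 1 without null vehicle 11. Log2 changes of the lower-numbered and the higher-numbered libraries correlated at 0.53 across genes. On the library score null vehicle 7 was at 0.686, with the lower-numbered null rhNGF libraries, and null rhNGF 22 at -0.247, among the null vehicle ones. Null vehicle 7 is itself lower-numbered and null rhNGF 22 higher-numbered, so each also lay on the side of its number set in WT.

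Ngf, the mouse gene for the factor given, was at 4.66 ± 1.48 TPM in null vehicle and 6.80 ± 1.20 TPM in null rhNGF cortex (0.59 ± 0.18, adjusted p = 0.082, and 0.0024 with the number set as a term; 0.51 and 0.68 within the number sets). Bdnf was -0.51 ± 0.26 (adjusted p = 0.16, and 0.02 with the term), Sgk1 -0.30 ± 0.12 (0.089, and 0.018 with the term) and Fkbp5 -0.25 ± 0.11 (0.12, and 0.043 with the term). Mecp2 (0.16), Irak1 (-0.02), Crh (-0.27), Ntrk1 (-0.15) and Ngfr (-0.15) did not pass in either fit.

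Camera called 9 lists, with 0 at an estimated correlation, and 39 of 100 splits of the same libraries called at least as many. Higher under rhNGF were the cytosolic ribosome (54 of 57 above 0, median 0.34, with Rpsa 0.46, Rps28 0.48, Rps11 0.44), complex I (34 of 37, 0.31, with Ndufb4 0.39, Ndufs8 0.46, and Ndufs1 at -0.38), complexes II to V (34 of 40, 0.31, with Atp5e 0.89, Sdhc 0.39, Cox5b 0.39) and the mitochondrial ribosome (0.23, with Mrpl2 0.47, Mrpl4 0.40, Mrpl10 0.38). So were glycolysis (0.31, with Eno2 0.43, Pkm 0.41, Pfkm 0.35), neighbours of Mecp2 on chromosome X (0.22, with G6pdx 0.38, Atp6ap1 0.37, Ssr4 0.36) and antioxidant genes (0.15, with Prdx5 0.43, Txn2 0.42, and Gclc at -0.45). Lower were voltage-gated channels (-0.36, with Scn8a -0.37, Kcnb1 -0.38, Cacna1d -0.42) and striatum markers (-0.69, with Pde10a -1.29 and Rarb -0.88). Camera adjusted p lay between 1.8e-08 and 0.036, and between 0.81 and 0.82 with an estimated correlation. Of these lists, 0 members were called over all genes tested, while adjusted over the list alone 26 members of complexes II to V were higher and 1 lower, 2 channels were higher and 5 lower, and the other 7 lists had 0. Of 27 members selected by the rule, 24 passed with the number set as a term, among them Rpsa (adjusted p = 0.0024), Cox5b (0.0033) and Scn8a (0.0032), and no striatum marker did. Within the lower-numbered and the higher-numbered libraries, the medians were 0.48 and 0.19 for the cytosolic ribosome, 0.45 and 0.17 for complex I, and -1.70 and 0.21 for striatum markers, which turned sign. Across genes, the change with rhNGF in null cortex correlated at 0.669 with the difference between the number sets in WT cortex.

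In WT cortex rhNGF changed no gene past the threshold: 0 genes were called by limma (696 at an unadjusted p under 0.05), 2 with the number set as a term (Lrrc45 and Clasrp), 0 within the lower-numbered and 1 within the higher-numbered libraries (Neat1). The 5 smallest p, none passing (adjusted p = 0.19 each), belonged to Carmil3 (0.55), Srrt (0.43), Col4a2 (0.48), Lrrc45 (0.57) and Sh3tc1 (-0.74). Ngf (0.17 ± 0.18), Bdnf (-0.08 ± 0.26), Ntrk1 (0.29 ± 0.18), Ngfr (0.19 ± 0.19), Sgk1 (-0.34 ± 0.12), Fkbp5 (-0.08 ± 0.11), Crh (-0.23 ± 0.19), Irak1 (-0.02) and Mecp2 (0.01) did not pass, with adjusted p of 0.98 or more.

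Camera called 12 lists in WT cortex, with 0 at an estimated correlation, and 17 of 100 splits called at least as many. Lower under rhNGF were complex I (37 of 37 below 0, median -0.10, with Ndufa1 -0.30, Ndufv2 -0.22, Ndufa4 -0.22), complexes II to V (40 of 40, -0.11, with Atp5j -0.20, Cox7c -0.19, Uqcrfs1 -0.14) and the cytosolic ribosome (-0.06, with Rpl22 -0.17, Rpl34 -0.18, Rps7 -0.15). Also lower were the mitochondrial ribosome (-0.04, with Mrpl18 -0.24, Mrpl13 -0.17, Mrpl33 -0.19), the TCA cycle (-0.06, with Mdh1 -0.21, Fh1 -0.18, Mpc1 -0.25) and mitochondrial dynamics (-0.07, with Slc25a5 -0.16, Vdac2 -0.14, Nrf1 -0.24). So were the glucocorticoid response (-0.10, with Tsc22d3 -0.43, Sgk1, Errfi1 -0.12) and the circadian clock (-0.13, with Ciart -0.52, Dbp -0.37, Bhlhe41 -0.17). Higher were markers of meninges (0.37, with Slc6a13 0.57, Col3a1 0.55, Bmp6 0.39), striatum (0.33, with Isl1 0.33, Rxrg 0.57, Gng7 0.42) and basal forebrain cholinergic neurons (0.22, with Zic4 0.38, Isl1, Ntrk1), and neighbours of Mecp2 (0.03, with Plxna3 0.50, L1cam 0.28, Taz 0.24). Isl1, in both the striatum and the basal forebrain list, was at 0.307 TPM in WT vehicle and 0.777 TPM in WT rhNGF cortex. Ntrk1 was at 0.243 and 0.603 TPM, so both genes were low. Camera adjusted p lay between 7.7e-07 and 0.015, and between 0.091 and 0.83 with an estimated correlation, and none of the 35 named members passed over all genes tested, with or without the number set as a term. Complex I had a median of -0.20 within the higher-numbered libraries and 0.000 within the lower-numbered ones.

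The interaction asks whether rhNGF acts differently in null and WT cortex. It called 0 genes by limma (2386 at an unadjusted p under 0.05) and 811 with the number set as a term. Within the lower-numbered and the higher-numbered libraries it called 0 and 1, again Neat1. The 5 smallest p, none passing, belonged to Arhgef28 (-0.76), Neat1 (-1.12), Traip (-0.96), Atp11a (-0.89) and Acot5 (0.81), with adjusted p between 0.28 and 0.33. Neat1 was at 13.2 ± 1.16 TPM in WT vehicle, 21.3 ± 5.93 in WT rhNGF, 25.6 ± 6.13 in null vehicle and 16.2 ± 4.78 TPM in null rhNGF cortex, and its interaction was -1.12 and -1.13 within the number sets. Of the genes always named, none passed: Ngf 0.42, Bdnf -0.42, Ntrk1 -0.45, Ngfr -0.35, Sgk1 0.04, Fkbp5 -0.17, Crh -0.04, Irak1 0.000 and Mecp2 0.15.

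Camera called 13 lists in the interaction, with 0 at an estimated correlation, and 15 of 100 splits called at least as many. Positive, so higher with rhNGF in null than in WT cortex, were complexes II to V (0.42, with Atp5e 1.15, Cox7c 0.40, Uqcrfs1 0.25), the cytosolic ribosome (0.42, with Rps25 0.37, Rps20 0.45, Rps23 0.35) and complex I (0.41, with Ndufa4 0.40, Ndufb4 0.54, Ndufv2 0.30). So were glycolysis (0.34, with Slc2a1 0.57, Pfkm 0.37, Pgk1 0.32), the mitochondrial ribosome (0.29, with Mrpl27 0.43, Mrps21 0.54, Mrpl33 0.32), antioxidant genes (0.25, with Prdx5 0.53, Sod2 0.29, Gpx4 0.55) and the TCA cycle (0.16, with Mpc2 0.28, Fh1 0.35, Sdhb 0.49). Negative were voltage-gated channels (-0.34, with Cacna1c -0.46, Kcnd3 -0.76, and Scn1b at 0.67) and markers of striatum (-1.05, with Isl1 -0.76, Pde10a -1.55, Rarb -1.16). So were those of choroid plexus (-0.93, with Enpp2 -1.20, Kl -1.66, and Rarres2 at 0.65), basal forebrain cholinergic neurons (-0.51, with Zic4 -0.77, Isl1, Slc5a7 -0.51), hippocampus (-0.44, with Man1a -0.79, Ahcyl2 -0.45, Spink8 -1.27) and meninges (-0.39, with Dcn -1.004, Slc13a4 -0.99, Bmp6 -0.55). Isl1 and Zic4 were low, with group means of 0.147 to 0.777 TPM and 0.662 to 1.41 TPM. Isl1 counts in both the striatum and the basal forebrain list. Camera adjusted p lay between 2.2e-12 and 0.048, and it was 0.68 for each list with an estimated correlation, and none of the named members passed. Of 38 members, 18 passed with the number set as a term, among them Ndufa4 (adjusted p = 0.039), Mpc2 (0.04) and Rarres2 (0.038). Within the lower-numbered and the higher-numbered libraries, the medians were 0.48 and 0.37 for the cytosolic ribosome and 0.45 and 0.38 for complex I. They were -1.66 and -0.01 for choroid plexus, -1.74 and -0.43 for striatum and -0.52 and -0.22 for hippocampus, and Bmp6 was at -1.10 and 0.01, each larger in size in the lower-numbered libraries.

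**Figure D4:**
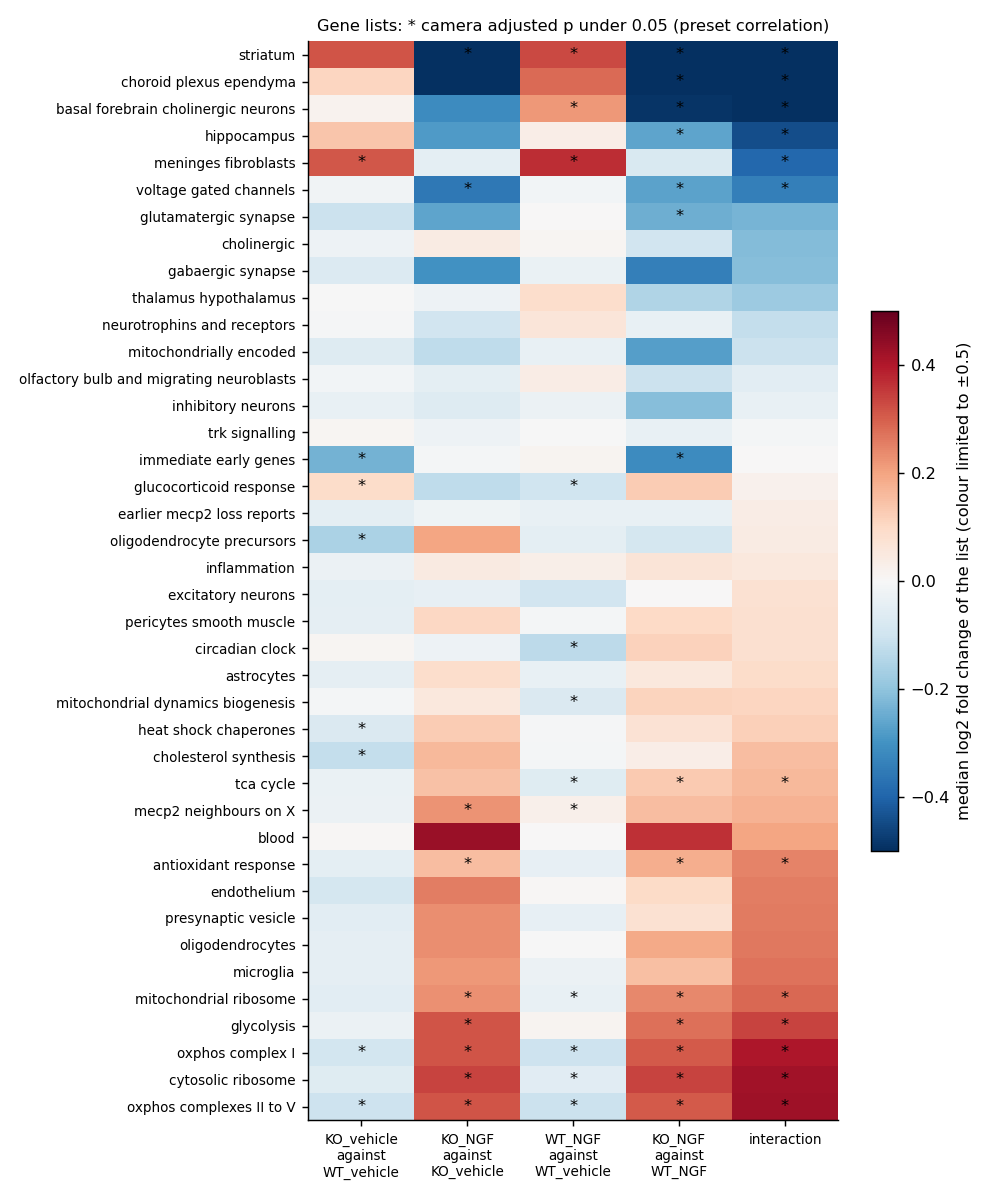
Median log2 fold change of the measured members of 40 gene lists, ordered by the interaction, in 5 comparisons, with the colour limited at 0.5 in size. Stars mark a camera adjusted p under 0.05 at the preset correlation, and none remains with an estimated correlation.

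Whether rhNGF moved the genes of the null difference back was examined over the 32 genes called under vehicle. Of these, 26 had the opposite sign for rhNGF in null cortex, and the correlation of both log2 changes across genes was -0.51 with a covariance of -0.133. Both comparisons share the null vehicle libraries, and unchanged rhNGF groups simulated for these fixed genes gave a mean correlation of -0.077 (95% of simulations between -0.485 and 0.33) and a mean covariance of -0.0103 (between -0.0744 and 0.0404). With separate null vehicle libraries for each comparison (20 ordered splits), the mean correlation was -0.46 and the mean covariance -0.1245. The 32 genes had been called with all null vehicle libraries, so these splits do not remove that selection. Over all 16904 genes tested the correlation was -0.404, against -0.348 in simulations of unchanged rhNGF groups, and with separate null vehicle libraries it was -0.089 on average (-0.382 to 0.313, covariance -0.0054). When the genes were called anew in each of 100 simulations of unchanged rhNGF groups, the correlation was -0.425 on average (95% between -0.837 and 0.176), the covariance -0.0774 (between -0.31 and 0.0211), and 70.6% of the called genes had opposite signs (95% between 42.2 and 92%), against 81.2% observed. The observed values lay within the spread of these last simulations. Those simulations called a median of 96 genes, against 32 observed, so they do not match the data and leave the question open.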

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

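The tests on the number sets, the gradient score, the GC trend, the striatum markers and the calls near Mecp2 were chosen only after these patterns were seen. Values of single libraries far from the other 5 of their group are listed first, by Dixon's test at the 95% level; chance flags about 1 in 20 groups, and 660 tests were made on named genes, with 48 found. KO_vehicle 7 was the highest of its group for Mrpl10 (68.9), Mrpl4 (62.8), Eno2 (1205), Atp6ap1 (466), Prdx5 (412), Pkm (1451), Ndufs8 (313), Cox5b (726), Sdhb (244), Scn1b (1174), Ndufa12 (615), Sod1 (733), Pcx (57.4), Atp5a1 (887), Mrps17 (71.5), Mrps27 (33.7), Mrpl27 (99.9), Mrps21 (214), Pgk1 (532) and Gpx4 (836) and the lowest of its group for Gclc (11.8), Pdgfra (10.4) and Trpc6 (0.9). WT_vehicle 2 was the highest of its group for Ngfr (1.34), AW551984 (3.47), Aqp1 (6.18) and Ecel1 (8.26) and the lowest of its group for Tbr1 (56.7). KO_vehicle 9 was the highest of its group for Srrt (118) and Traip (6.16). WT_NGF 14 was the highest of its group for Rps7 (462) and Mpc2 (121). KO_NGF 19 was the lowest of its group for Grp (5.16) and Kcnb1 (28.7) and the highest of its group for Col4a2 (14.96). KO_NGF 21 was the highest of its group for Atp5j (306) and Acot5 (9.27). WT_vehicle 1 was the highest of its group for Mrpl13 (52.7). WT_vehicle 3 was the highest of its group for Vamp1 (199). WT_vehicle 4 was the highest of its group for Man1a (10.4). WT_vehicle 5 was the highest of its group for Slc16a14 (4.08) and the lowest of its group for Nr4a3 (3.80). WT_NGF 15 was the highest of its group for Ecel1 (11.4). WT_NGF 18 was the highest of its group for Slc16a14 (5.43). KO_NGF 22 was the lowest of its group for Uqcrfs1 (151). KO_NGF 23 was the highest of its group for Cyp51 (30.03) and the lowest of its group for Fkbp5 (13.3). KO_NGF 24 was the lowest of its group for Mecp2 (1.78). Ranks and gaps were taken on the scaled log2 values, while the values printed are TPM as deposited. Those of Atp5j, Uqcrfs1 and Col4a2 are therefore not the extreme deposited TPM of their group, and that of Mpc2, highest after scaling, is the lowest deposited one. WT_vehicle 3 had the lowest mitochondrial share of its group (8.42%), and KO_vehicle 7 the fewest genes at 1 TPM or more (13825). Genes of energy metabolism and the mitochondrial ribosome make up most of the list of KO_vehicle 7, which are correlated and not separate events.

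The interaction of rhNGF and genotype was called in 13 gene lists by camera at the preset correlation and in 0 with an estimated correlation. The median interaction was 0.405 for complex I, 0.423 for complexes II to V, 0.289 for the mitochondrial ribosome, 0.339 for glycolysis, 0.161 for the TCA cycle, 0.418 for the cytosolic ribosome and 0.248 for antioxidant genes. It was -0.341 for voltage-gated channels, -0.394 for meninges, -0.93 for choroid plexus, -1.049 for striatum, -0.444 for hippocampus and -0.512 for basal forebrain cholinergic neurons. With an estimated correlation the adjusted p was 0.68 for each, and 15 of 100 splits called at least as many lists, with 15 the highest other count, so chance cannot be excluded.

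Nuclear genes of ribosomal proteins and oxidative phosphorylation were higher in null cortex after rhNGF, with a mean difference of 0.288 (exact permutation p = 0.043 over 924 splits, and 0.01 over the 400 splits inside the number sets). Mitochondrially encoded genes, not part of this mean, went the other way (median -0.13, 2 of 13 above 0, and -0.30 and -0.13 within the lower-numbered and higher-numbered libraries; camera adjusted p = 0.14). Correcting for the library score by its slope in WT libraries left 0.113 (exact permutation p = 0.024 and 0.03), with 0.21 in the lower-numbered and 0.015 in the higher-numbered libraries, which cannot tell the library gradient from an effect. Removing the GC trend left 0.286, so a GC trend does not account for it. An effect of rhNGF (permutation p of 0.01 inside the number sets) could not be told from the gradient either, and over the 21 exact tests the smallest adjusted p was 0.0525.

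Striatum markers varied by up to 2.66 log2 units within a group, and their estimated inter-gene correlation within groups was 0.843, but complex I (0.688), the cytosolic ribosome (0.668) and mitochondrially encoded genes (0.585) also passed 0.5, so whether neighbouring tissue was carried in the dissection cannot be told from it. An effect of rhNGF or genotype does not account for differences between libraries of the same group, and the permutation p of the spread of the 4 group means was 0.49 (0.4918, 100000 resamples). Mean log2 deviations of striatum and choroid plexus markers were high together in KO_vehicle 8 (1.678 and 1.12), KO_vehicle 9 (1.388 and 1.348), WT_NGF 15 (1.55 and 1.732) and WT_vehicle 2 (0.82 and 1.654). They parted in WT_NGF 16 (0.861 and -0.732) and WT_NGF 14 (-0.846 and 0.553). Joint peaks would go with carried tissue in those libraries, which was not tested.

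Calls were more frequent next to Mecp2. Within 5 Mb, 3 of 73 tested genes were called under vehicle (Nsdhl, Haus7 and Irak1; odds ratio 25.7, Fisher exact p = 0.00032, two-sided) and 2 under rhNGF (Irak1 and Plxna3; odds ratio 4.81, Fisher exact p = 0.069). The excess under vehicle (Fisher exact p = 0.0003185, 73 genes near Mecp2 and 16830 elsewhere) prompted the test, and it did not pass in the separate libraries under rhNGF. Sequence carried along with the targeted locus and regulation by Mecp2 acting on all its targets alike therefore both stay open, and TPM hold no sequence variants.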

How the results depend on the processing

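No named gene with a call changed direction under the alternatives run for single genes, which leaving out 1 library was not. The difference of long genes between null and WT vehicle cortex stayed between 0.034 and 0.104 and the reversal correlation between -0.584 and -0.317 under the alternatives run for them, which leaving out 1 library and fitting only the 2 groups were not. Counts of called genes moved far more, and the cause was not tested. For null against WT under vehicle (32 genes), median-of-ratios factors gave 57, a filter of 1 TPM 51 and only the 2 groups compared 21. For null against WT under rhNGF (101 genes), these gave 156 (100 higher, 56 lower), 189 (130 higher, 59 lower) and 10, and no filter 61. For rhNGF in null cortex (2 genes), only the 2 groups compared gave 0. No filter gave 1 interaction gene and 16 lists for rhNGF in null cortex. Leaving out 1 library gave 15 to 32 genes under vehicle, 31 to 789 under rhNGF, 0 to 5723 for rhNGF in null cortex, and 0 to 0 for rhNGF in WT cortex and for the interaction.

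The next alternatives were chosen after seeing the data. Pseudocounts of 0.1 and 0.5 TPM moved no count by over 1.5 times, and TPM as deposited gave 0 genes for rhNGF in null cortex. For the others, counts are in the order null against WT under vehicle, rhNGF in null, rhNGF in WT, null against WT under rhNGF, and interaction. The number set as a term gave 157, 6878, 2, 5015 and 811. The lower-numbered libraries alone gave 2, 3548, 0, 5 and 0, with 2 lists for rhNGF in WT. The higher-numbered ones gave 7, 0, 1, 4491 and 1, with 8 interaction lists. The score along the WT division as a covariate gave 341, 199, 37, 608 and 2, with 23 lists for null against WT under rhNGF. The first 2 residual principal components gave 645, 8287, 55, 7282 and 5773, with 13 lists under vehicle. Sample quality weights gave 245, 6821, 0, 3406 and 2519 by the gene-by-gene method and 238, 6533, 0, 479 and 3 by the default method, which did not converge, so the interaction depends on how the weights are estimated. Without KO_vehicle 7 and WT_vehicle 3 the counts were 13, 5628, 0, 204 and 0, with 7 lists for rhNGF in WT. Removing the GC trend gave 150, 13, 0, 764 and 0, with 15 lists for rhNGF in null.

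For gene lists, the estimated correlation gave 0 in all 5 comparisons, and fry gave 2, 0, 1, 4 and 2. With the number set as a term fry gave 2, 12, 1, 15 and 7, with the score as a covariate 2, 0, 3, 13 and 6, and with 2 residual components 4, 15, 3, 18 and 12, while the estimated correlation gave 0 each time. Some list medians turned sign: within the lower-numbered libraries chaperones under vehicle (0.001) and, for rhNGF in WT, the mitochondrial ribosome (0.030), the cytosolic ribosome (0.020) and the circadian clock (0.005); within the higher-numbered libraries striatum for rhNGF in null (0.210) and neighbours of Mecp2 for rhNGF in WT (-0.068, and -0.009 with quality weights). The median of all genes shifted by over 0.1 only with TPM as deposited in the interaction (-0.108). The planned count-based tests, voom weights and surrogate variables were not run, because TPM are not counts. The sequencing depth is unknown, so the limit it sets on low genes cannot be given.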

Other observations

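The tests with the number set as a term and of the composition of the gradient were chosen only after the gradient was seen. A small set of genes differed alike between null and WT cortex in separate libraries. Irak1 (log2 change 0.91 under vehicle and 0.91 under rhNGF), Fgf11 (-1.002 and -1.27), Cacna1g (-0.74 and -0.83), Tnnc1 (-1.71 and -1.23), Clcnka (0.74 and 1.03) and Bmper (0.66 and 0.72) were among the 11 genes called in both genotype comparisons, all with the same sign. A genotype effect carried by both treatments would give such an overlap. The 11 genes, Mecp2 itself among them, are far above the 0.038 and 0.056 for unrelated lists, and each passed in separate libraries. They are fewer than the 0.5 of the 32 genes set beforehand as the mark of a genotype effect carried by both treatments. That test therefore leaves open whether most of the 32 genes repeat. Fkbp5, called under vehicle (0.59), was 0.42 under rhNGF and did not pass there.

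The gradient between libraries was present in every group. Across genes, the difference of the number sets in WT cortex had a Spearman correlation of 0.677 with transcript GC content and -0.298 with transcript length, which fits a difference in transcript composition, such as RNA quality or library preparation could give, though neither was tested. The change with rhNGF in null cortex had 0.658 and -0.327, and null against WT under vehicle -0.17 and 0.213. Removing a smooth GC trend lowered the share of the residual first component from 40.7 to 24.8%. No label names a batch or a quality value per library, so the source was not identified.

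Other splits of the libraries show what chance can give (100 per comparison, counting the real one). For genes called in null against WT under vehicle, 2 splits called at least the real 32, with 34 the highest other, so chance is unlikely. For rhNGF in null cortex, 5 splits reached the real 2 genes and the highest other called 8478, from exchanging KO_vehicle 7 with KO_NGF 22, and chance cannot be excluded. On the library score KO_vehicle 7 (0.686) lay with the lower-numbered KO_NGF libraries and KO_NGF 22 (-0.247) among the KO_vehicle ones. KO_vehicle 7 is itself lower-numbered and KO_NGF 22 higher-numbered, so each also lay on the side of its number set in WT. An exchange of their labels was not tested, since no value marks the treatment, and the labels were kept. For null against WT under rhNGF, 5 splits reached the real 101, and the highest other, 9095, followed the lower-numbered and higher-numbered libraries, so chance cannot be excluded. For rhNGF in WT cortex and for the interaction, 100 splits reached the real 0, with highest others of 2 and 1.

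With the number set as a term and splits kept inside it, 4 splits reached the real 157 genes under vehicle (highest other 1980), so chance is unlikely but single splits can exceed the real count. In the other comparisons only the real split, 1 of 100, reached its count: 6878 for rhNGF in null (highest other 6096, exchanging KO_vehicle 7 with KO_NGF 20, with 6 splits over 1000), 2 for rhNGF in WT (1), 5015 for null against WT under rhNGF (5) and 811 for the interaction (1). This term was chosen after the gradient was seen, and it was fitted to 3 libraries a side in each group, so these counts need new samples to be relied on. For gene lists the splits that reached the real count were 51 under vehicle (real 8, highest other 16), 39 for rhNGF in null (9, 20), 17 for rhNGF in WT (12, 19), 10 for null against WT under rhNGF (14, 18) and 15 for the interaction (13, 15), so chance cannot be excluded for any of them. The long-gene difference of 0.063 was reached by 42 splits (highest other 0.153), so chance cannot be excluded.

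Nuclear copies of mitochondrial sequence took 4.96 to 9.89% of a library and mitochondrially encoded genes 8.42 to 18.6%, and since they share sequence, the division of reads between them is uncertain.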
